A study of Mus musculus with 3 samples.

How the data were processed

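Total RNA of 3 mouse cultures was measured on 1 array each: fibroblasts given 7 factors, fibroblasts given 8 factors, and thyroid follicular cells grown as a primary culture. Groups were taken from the sample titles and source names, and per the labels each group holds 1 sample. Per the labels' protocols, the RNA was labelled with Cy3 by the Quick Amp one-colour method. The arrays are 4x44K Whole Mouse Genome arrays per the file headers. Per the file headers the induced cultures lay on 1 slide read in 1 scan, and the primary culture lay on a second slide read in another scan.

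The deposited values are intensity values. Per the file headers, Feature Extraction 11.5.1.1 subtracted background from the spot signals and corrected trends across each array to give a processed signal; the submitters' processing notes name version 10.5 instead. The design text of the submitters names a shift to the 75th percentile, but the deposited value table equals the processed signal of each array on the linear scale, with no scaling between arrays. Each array file also gave the error of the processed signal from the scanner software's error model, the median signal of the spot and of its local background, and marks for spots well above background, saturated or unlike their copies.

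Values were recomputed from the array files. Control spots and spots marked as outliers were left out, which removed 3 probes entirely, and the 245 probes spotted 10 times were averaged on the log2 scale. This left 41171 probes. Signals were put on a log2 scale and the 75th percentile of each array was subtracted. Probes were named by matching their RefSeq accessions to a table of mouse annotation GRCm38.p6, used for names only; the grid of the arrays refers to mm9 per the file headers, and no coordinates are given. Of the probes, 27815 (67.6%) received 1 gene name and 0 received several. Among the 27220 probes with an mRNA accession 26936 were named. The 13356 unnamed probes carry other identifiers or accessions outside that table and were not analysed here. The named probes cover 18951 genes, of which 6716 have several probes, and a gene was represented by the probe with the highest mean signal over the 3 arrays.

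A gene was compared where it was well above background on at least 1 of the arrays compared. If well above background on both, the log2 difference was taken as measured, and a 2-fold difference counted as higher or lower. If well above background on 1 array only, the other value was replaced by the lowest signal of any probe well above background on that array, which makes the difference a bound, printed as "at least". Where that replacement lay above the measured signal, the bound pointed the wrong way and the difference was set to 0. Such genes still counted as measured members of a list. Where the brightest probe lay below that mark on an array and another probe of the gene did not, the gene was left out of such calls. With 1 array per group no test between groups was made. The scanner error of a difference, which covers the reading of a spot and not the culture, had a median of 0.207 for the genes named in the comparison of 7 factors with primary cells, 0.206 for 8 factors with primary cells and 0.204 for 8 with 7 factors, and a highest value of 0.438. Its lowest value was 0.204 in every comparison and was shared by many bright genes. For those genes it is set by the error model and was not measured from repeated spots. Copies of a probe on the same array had a median SD of 0.07, 0.10 and 0.06 on the 7-factor, 8-factor and primary arrays.

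For groups of genes, 29 lists with 492 genes were written before the data were examined, and 469 of the genes have a probe. A list was summarised by its median log2 difference over measured members, floored as described. Its percentile was taken among 10000 random lists of the same size, drawn to match the members on mean signal in 20 bins. That percentile describes these arrays and is not a p-value, because genes within a culture are not independent. Overlap between the comparisons with primary cells was set beside the count for independent lists and beside 100 simulations of unchanged arrays set against a shared array. Similarity was given as correlation across genes.

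The genes named in the text were chosen by a rule written before the data were examined. In each comparison it takes every measured member of the delivered factors and thyroid function lists, up to 4 members of each other list with the largest differences, the 8 largest measured differences in each direction, and the 4 largest bounds in each direction, leaving out predicted genes and clones. The text names a subset of these, and some genes that the rule takes are not reported here. The second probe of Hhex was picked for mention after its values were seen, and so was the list of gastric and intestinal mucous genes.

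Alternatives chosen before the data were examined were normexp background correction with an offset of 50, quantile normalization, scaling to the median of each array, the deposited value table, the median level over the probes of a gene on each array, genes well above background on both arrays only, no filter on dim genes, and a threshold of 3-fold. Normexp was applied to median spot signals, because the array files do not hold the mean signals that had been planned. Chosen after the first results were 2 more: no scaling between arrays, and a floor raised to 25% of the 75th percentile signal. The median difference of all genes measured on both arrays was -0.08, -0.14 and -0.09 in the comparisons of 7 factors with primary, 8 factors with primary and 8 with 7 factors; scaling to the median made these 0.22, 0.11 and -0.15.

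The calls were tested on simulated data for the comparison of 8 factors against 7 factors, with 200 genes given a known change on top of noise drawn from the real differences of these arrays. Of 100 genes changed by 1.5 on the log2 scale 75 were recovered, of 50 changed by 2 there were 46, and of 50 changed by 3 there were 47. Of 16344 genes with no change added, 8.66% were called, a share that includes real differences between the cultures. Since the noise was drawn from the observed differences, this share had to lie near that of the real comparison (4.54% higher and 4.04% lower). It is not a rate of false calls and cannot tell real calls from noise. Of 100 null lists of 20 genes, 7 lay outside the central 95% of random lists. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and normexp in R 4.3.3 with limma 3.58.1.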

Results

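The series holds 3 one-colour microarrays of mouse RNA, 1 for each group, and asks how closely fibroblast cultures given thyroid and reprogramming factors resemble cultured thyroid cells. The 7-factor culture was made from embryonic fibroblasts of ICR mice infected with retroviruses for the thyroid transcription factors Pax8, Nkx2-1 and Foxe1 and the reprogramming factors Oct3/4 (Pou5f1), Sox2, Klf4 and c-Myc (Myc). The 8-factor culture received the same set plus Hhex, a homeobox factor of the developing thyroid. Both were collected on day 21, after a last phase in medium with thyroid stimulating hormone and iodide. The primary culture consisted of thyroid follicular cells of adult ICR mice kept for 1 week in that medium. There were no replicates, so no difference below has a replicate check and no p-value is given; the number of arrays limits the precision. Signals are log2 values relative to the 75th percentile of the array, and a gene counts as higher or lower from a 2-fold difference.

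The share of spots well above background was 78.2% on the 7-factor array, 78.2% on the 8-factor array and 64.2% on the primary array. The 75th percentile of the signal was 2190 (intensity units) on the 7-factor array, 2535 on the 8-factor array and 504 on the primary array, which was thus 4.34 and 5.03 times dimmer than the others by this measure. Spike-in control probes went otherwise. Their mean signal on the 7-factor and 8-factor arrays was 0.92 and 0.45 times that on the primary array. Spike-ins were therefore not dimmer on the primary array, and they differed between the induced arrays. The primary array also lay on another slide and was scanned in another run, so batch and group cannot be told apart in any comparison with it. Across 16501 genes, the induced cultures resembled each other (Pearson r = 0.986, Spearman rho = 0.987) more than either resembled the primary culture (7 factors, r = 0.852 and rho = 0.858; 8 factors, r = 0.853 and rho = 0.861). These correlations run across genes, which are not independent replicates.

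The comparison of the 7-factor culture with the primary culture asks how close its thyroid gene expression lay to that of primary cells. The series holds no array of uninfected fibroblasts. What the induced cultures gained, lost or kept from their starting cells therefore cannot be told. Thyroglobulin (Tg), the protein on which thyroid hormone is built, was 3612-fold lower in the 7-factor culture, a log2 difference of -11.82 with a scanner error of 0.20. Of the 18 measured genes of the thyroid function list, 13 were lower and 3 higher than in primary cells. The lower ones included the iodotyrosine deiodinase Iyd (at least 320.4-fold, not well above background in the induced culture), the iodide transporter Slc5a5 (at least 23.2-fold), the thyrotropin receptor Tshr (9.13-fold), the dual oxidase maturation factor Duoxa2 (81.7-fold), the deiodinase Dio1 (61.2-fold), the anion exchanger Slc26a4 (16.3-fold) and the cadherin Cdh16 (33.1-fold). The smaller differences among the lower genes were those of Duox1 (2.32-fold), Lrp2 (4.88-fold) and Slc5a8 (7.25-fold). Genes of this list that were higher in the induced culture were the trefoil peptide Tff3 (197-fold), the potassium channel subunit Kcne2 (at least 94.2-fold) and the deiodinase Dio2 (6.25-fold), while Kcnq1 and Ano1 differed by -0.37 and 0.49. The list median was -3.61, below all of 10000 random lists matched on signal (central 95% from -1.09 to 0.66).

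Among the delivered factors, Sox2 was 10.4-fold and Myc 5.88-fold higher in the 7-factor culture than in primary cells. Pax8 was 169-fold, Nkx2-1 511-fold and Foxe1 5.59-fold lower. Klf4 differed by -0.65, and Pou5f1 lay near background on every array, with levels of -7.33, -7.46 and -5.76. Hhex, which this culture did not receive, was 9.16-fold lower. The probes of Myc disagreed: its brightest probe and another differed by 2.56 and 2.28, and the remaining one by -2.44. The files hold no probe sequences, so it is unknown which of these probes lie in the part of each transcript that the viruses carried, and a low value does not show that a factor was absent.

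**Figure D1:**
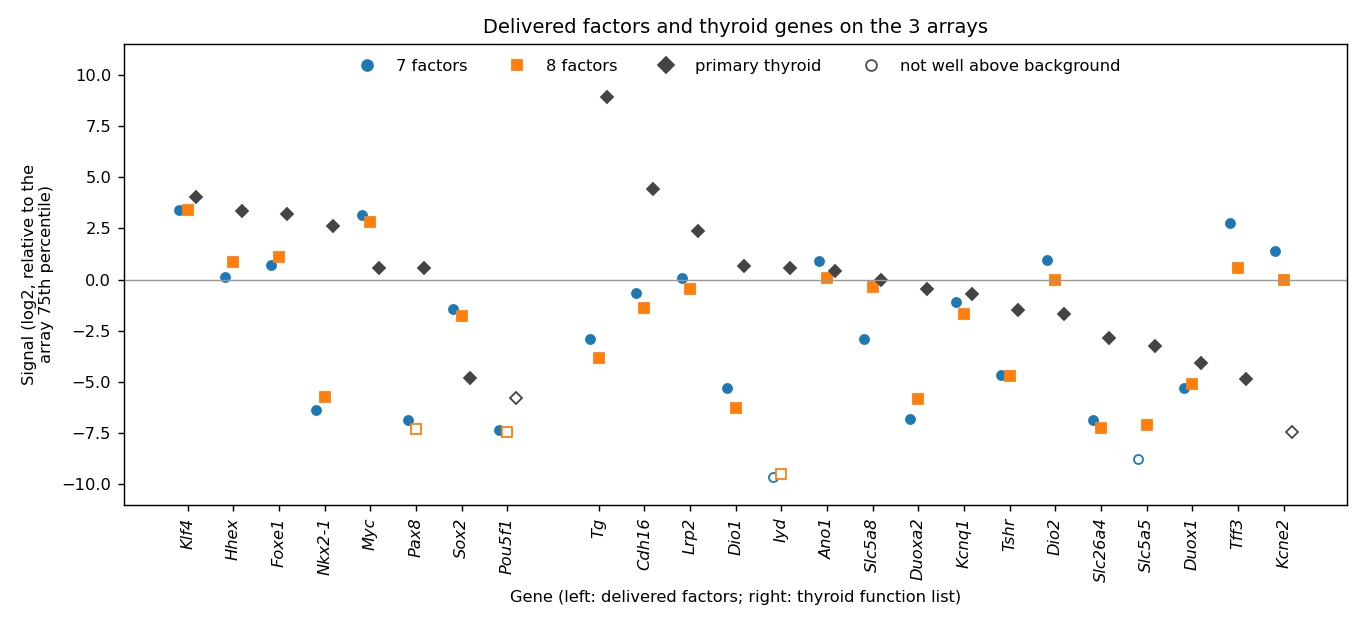
Signal of the delivered factors and of the members of the thyroid function list named in the text on the 7-factor, 8-factor and primary arrays, 1 array each, as log2 relative to the array's 75th percentile, with open symbols for probes not well above background; heights are comparable between arrays within a gene, not between genes. Tg lay at 8.89 in primary cells against -2.93 and -3.85 in the induced cultures, and Tff3 and Kcne2 lay the other way round.

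Epithelial genes were lower in the 7-factor culture, with 22 of 25 measured members lower and 0 higher. The clathrin adaptor subunit Ap1m2 was 666-fold, the tricellular junction protein Marveld2 114-fold, the protease inhibitor Spint1 66.4-fold and the membrane protease St14 57.8-fold lower. The list median was -4.36, below all 10000 matched random lists (central 95% from -0.64 to 0.62). Genes of fibroblasts and their matrix went the other way, with 20 of 30 higher and 1 lower. The collagen chains Col6a1 and Col6a3 were 23.3-fold and 14.7-fold, the proteoglycan Lum 12.8-fold and the mesenchymal factor Twist2 13.6-fold higher (dimmer probes of Col6a3, 1.40 and -1.25, neither of them above background in primary cells), and the list median of 2.36 lay above all random lists (central 95% from -0.36 to 0.55).

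Hox genes and imprinted growth genes, which mark embryonic mesenchyme and fetal growth, were also mostly higher in the 7-factor culture. Of 28 measured Hox genes, 20 were higher and 1 lower, among them Hoxc9 (at least 151-fold), Hoxa7 (at least 103-fold), Hoxd4 (46.1-fold) and Hoxb9 (37.6-fold), with a list median of 2.43. Of 13 imprinted growth genes, 8 were higher and 1 lower. Igf2 was 339-fold, Dlk1 at least 84.2-fold, Mest 33.0-fold and Peg3 at least 33.9-fold higher, with a list median of 2.22. Both medians lay above all 10000 matched random lists. The imprinted median passed their range (upper end 0.83) by less than its bootstrap SD of 1.42. A shift of that list was left undecided. Cell cycle genes had a median of 0.80, with 11 of 24 higher and 1 lower, Kif11 leading at 10.7-fold, although its dimmer probe differed by -1.51. In the p53 and senescence list (median 1.04) 7 of 14 were higher, among them Cdkn2a (9.04-fold) and Cdkn1a (3.89-fold), while the stress cytokine Gdf15 was 19.3-fold lower. The medians of the cell cycle and p53 lists lay at percentiles 99.6 and 99.8 of the matched random lists. Each passed the upper end of the range (0.64 and 0.76) by less than its bootstrap SD (0.18 and 0.45). Shifts of these lists were left undecided.

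Markers of other cell types also differed between the cultures. Of 18 measured leukocyte genes, 17 were lower in the 7-factor culture, with a median of -6.59, the lowest of the 29 lists. The complement genes C1qa and C1qc of macrophages were 1905-fold and 925-fold, the surface glycoprotein Cd52 1142-fold and the integrin Itgam 328-fold lower. Hormone genes of the neighbouring C cells and parathyroid cells were lower as well: parathyroid hormone (Pth) by at least 15276-fold, chromogranin A (Chga) by 869-fold and calcitonin (Calca) by 224-fold, with 9 of 10 genes lower and a median of -3.79. A second probe of Calca differed by 0.04. The inflammation list had 14 of 20 genes lower (median -2.25), among them lipocalin Lcn2 (431-fold) and the cytokines Il1b (at least 315-fold) and Tnf (at least 123-fold). Stratified epithelium genes were lower in 11 of 14 cases (median -2.82), with keratins Krt17 and Krt5 lower by 187-fold and 75.2-fold. Lung list genes had a median of -2.61; the surfactant proteins Sftpd and Sftpa1 were 428-fold and at least 132-fold lower and the club cell protein Scgb1a1 was at least 68.2-fold higher. The percentiles of these medians among matched random lists were 0 (leukocyte), 0.01 (C cell and parathyroid), 0 (inflammation), 0 (stratified epithelium) and 0.05 (lung).

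Muscle and signalling lists had negative medians as well. Genes at least 2-fold lower numbered 12 of 12 for skeletal muscle, 16 of 19 for the interferon response and 7 of 11 for the TGF-beta response. They numbered only 6 of 12 for smooth muscle and contractile genes, where 2 were higher, and 6 of 15 for ER stress, where 9 were under 2-fold. Medians were -2.26 for skeletal muscle (percentile 1.25; myoglobin Mb 43.2-fold lower), -1.97 for the interferon response (percentile 0.02; Irf7 37.3-fold lower), -1.94 for the TGF-beta response (percentile 0), -1.10 for smooth muscle and contractile genes (percentile 0.8; Des -4.25) and -0.89 for the ER stress response (percentile 0.08; Pdia4 5.18-fold lower). The median of the delivered factors was -1.57 (percentile 0.94). For skeletal muscle, smooth muscle and delivered factors the random lists had lower ends of -2.07, -0.84 and -1.20. Their medians passed these by less than their bootstrap SDs of 0.56, 0.60 and 2.01. Shifts of these lists were left undecided. Endothelial genes had a median of -1.42 (percentile 3.17), with Robo4 at least 231-fold lower, and liver genes one of -1.77 (percentile 5.68), with fibrinogen Fgb at least 178-fold higher and alpha-fetoprotein Afp 50.2-fold lower; both medians lay inside the range of random lists. Without scaling between arrays, the medians of the interferon, TGF-beta, smooth muscle, ER stress, endothelial and liver lists turned positive; leaving out scaling adds the same amount to every gene measured on both arrays. The remaining lists also lay inside the range of random lists. Their medians were -0.27 for pluripotency, -0.42 for endoderm and foregut, 0.00 for kidney, 0.00 for neural and glial genes, 0.38 for adipocyte genes, 0.08 for cartilage and bone, 0.63 for the cAMP response, -0.33 for sex-linked genes and -0.29 for housekeeping genes. The medians of 0.00 fall on bounds that were set to 0, so they do not show unchanged expression. Single members of these remaining lists still differed widely. Fbxo15, a marker of reprogrammed cells, was at least 90.2-fold and the morphogen Shh at least 26.0-fold higher. The neural factor Zic1 was at least 72.5-fold and the hypertrophic cartilage collagen Col10a1 at least 87.1-fold higher. Their lists went both ways. Pluripotency had 2 of 16 genes higher and 5 lower, and endoderm and foregut 3 of 14 higher and 6 lower. Neural and glial genes had 5 of 15 higher and 5 lower, and cartilage and bone 4 of 12 higher and 3 lower. Housekeeping had 3 of 13 genes higher and 2 lower, with Actb 4.79-fold and Rplp0 4.60-fold lower. Another probe of Rplp0 differed by -0.77.

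**Figure D2:**
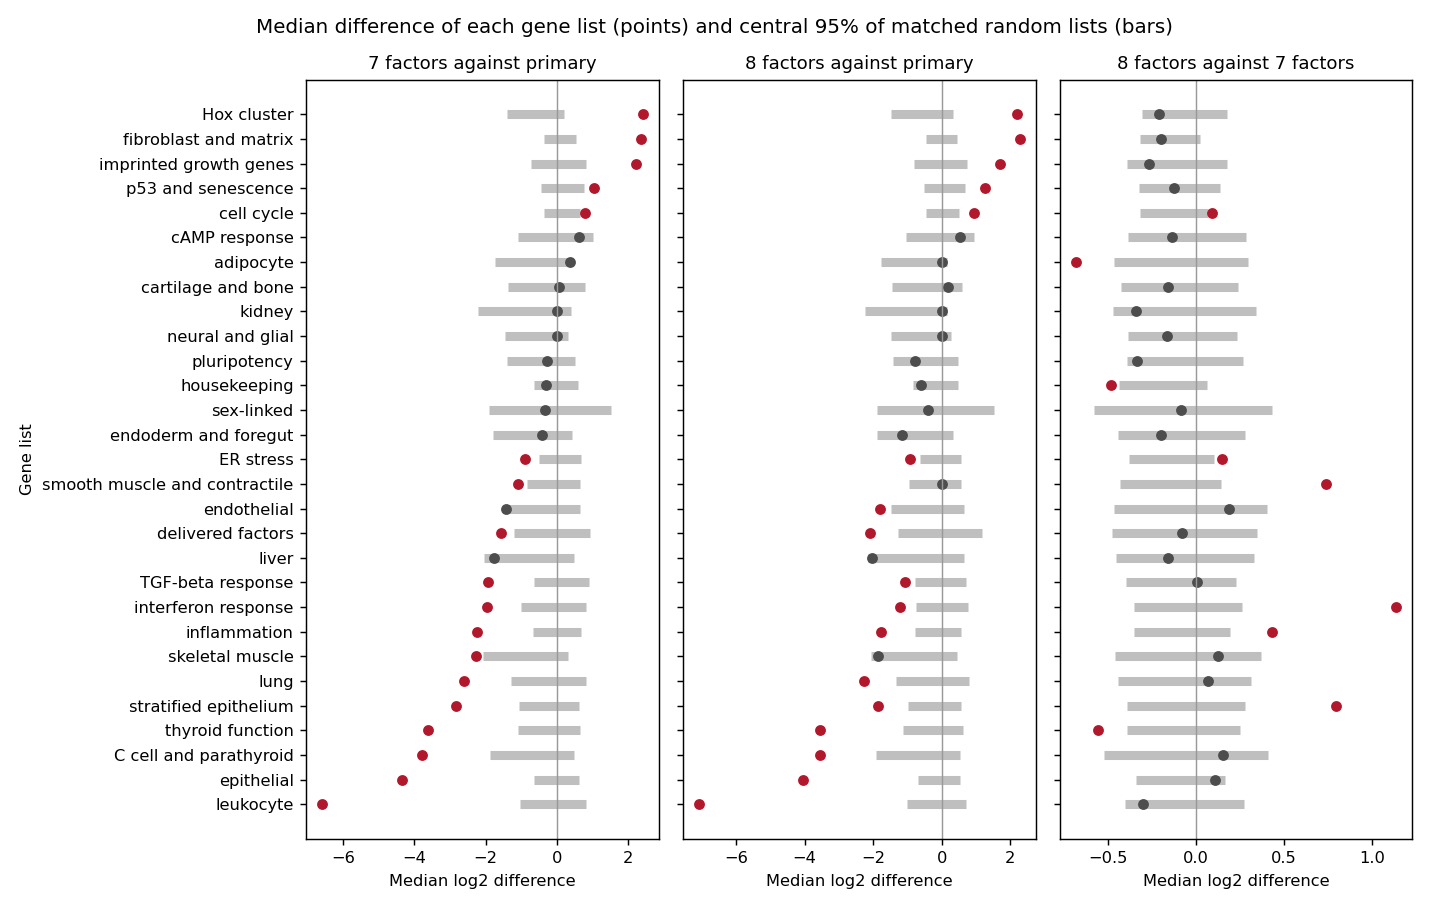
Median log2 difference of each of the 29 gene lists (points) in each comparison, with bars for the central 95% of 10000 random lists matched on signal; red points lie outside that range. The leukocyte list was lowest in both comparisons with primary cells (-6.59 and -7.08), and the interferon list was highest in the comparison of 8 with 7 factors (1.14).

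The largest differences between the 7-factor and the primary culture reached beyond these lists. The calcium-activated chloride channel regulator Clca1 was 1274-fold, the gastric trefoil peptide Tff1 777-fold, the secreted peptide Slurp1 323-fold and the slow myosin heavy chain Myh7 284-fold higher. The gastrokine Gkn2 was not well above background in primary cells and was at least 811-fold higher. The RNA-binding protein Rbm24 was 169-fold and the surface antigen Cd109 138-fold higher. At the other end, platelet factor Pf4 was 4022-fold, the survival gene Bcl2a1b 1373-fold and the monocarboxylate transporter Slc16a11 1279.7-fold lower. Chemokine Cxcl3 and the myeloid receptor Clec5a were not well above background in the 7-factor culture and were at least 1678-fold and at least 2022-fold lower.

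In all, 3078 genes were at least 2-fold higher and 4371 at least 2-fold lower in the 7-factor culture, of 16152 compared, and 362 and 992 passed 10-fold. Where a gene called on its brightest probe had a second measured probe, the second pointed the same way in 82.7% of 1935 cases and also passed 2-fold in 58.6%. Dim genes drew the balance towards lower calls: with genes split by level into 10 groups of equal size, the median difference was -1.93 in the dimmest group and between -0.30 and 0.30 in the 8 brightest. Scaling to the median gave 4218 higher and 3694 lower genes, a floor raised to 25% of the 75th percentile signal gave 2329 higher and 2162 lower genes, normexp background correction gave 2459 and 4807, and without scaling 11208 were higher and 1140 lower. List medians without scaling were -1.49 for thyroid function, -2.24 for epithelial, -4.47 for leukocyte, -1.67 for C cell and parathyroid, -0.70 for stratified epithelium and 4.48 for fibroblast and matrix genes.

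**Figure D3:**
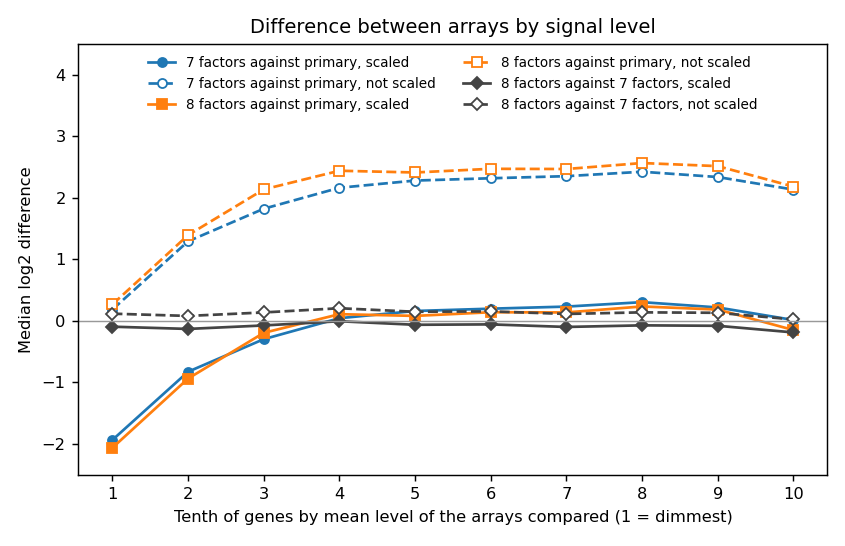
Median log2 difference in 10 equal groups of the genes measured on both arrays, ordered by mean level from dimmest to brightest, with filled symbols after scaling to the 75th percentile and open symbols without scaling. In the dimmest group, the median of the 7-factor minus the primary array was -1.93 after scaling and 0.19 without, and the comparison of 8 with 7 factors stayed flat.

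The comparison of the 8-factor culture with the primary culture asks the same with Hhex added. Thyroid genes were again far lower than in primary cells, with Tg 6865-fold, Dio1 122-fold, Duoxa2 41.3-fold, Slc5a5 14.5-fold and Tshr 9.33-fold lower. Pax8 and Iyd were not well above background in the 8-factor culture and were at least 228-fold and at least 350.2-fold lower. Of the thyroid function list, 12 of 18 genes were lower and 3 higher, the higher ones being Kcne2 (at least 35.5-fold), Tff3 (42.7-fold) and Dio2 (3.10-fold), and the median was -3.54. Slc5a8 differed by -0.34 from primary cells. Among the factors, Nkx2-1 was 329.6-fold and Foxe1 4.24-fold lower, and Sox2 8.10-fold and Myc 4.78-fold higher, although another probe of Myc differed by -1.76. Hhex was 5.52-fold lower on its brightest probe, while its other probe was 1.54-fold higher.

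Epithelial genes were lower in 21 of 25 cases (median -4.06; Ap1m2 309-fold, Marveld2 142-fold), and fibroblast and matrix genes were higher in 19 of 30 (median 2.27; the matrix protein Dpt at least 17.2-fold, Col6a1 15.4-fold). Hox genes (median 2.19, Hoxc9 at least 126-fold) and imprinted growth genes (median 1.71, Igf2 281-fold) were mostly higher. The thyroid and epithelial medians lay below, and the fibroblast, Hox and imprinted medians above, all 10000 matched random lists. Leukocyte genes were lower in 18 of 19 cases (median -7.08; C1qc 2619.9-fold, Adgre1 522-fold), as were C cell and parathyroid genes in 9 of 10 (median -3.57; Pth at least 16865-fold, Chga 2195-fold), at percentiles 0 and 0.01. Contractile genes had a median of 0.02, at percentile 67.6, with Myl9 3.20-fold higher and Des 8.96-fold lower. The interferon list had a median of -1.23 (percentile 0.22) and the inflammation list one of -1.78 (percentile 0); without scaling these were 1.101 and 0.55.

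In the 8-factor culture 2874 genes were higher and 4447 lower than in primary cells, of 16161 compared, and 310 and 986 passed 10-fold. Both induced cultures shared 2304 higher and 3859 lower genes, against 557 and 1223 for independent lists of these sizes, and 17 genes went opposite ways. Since both were set against the same primary array, unchanged arrays would share some calls too. In 100 simulations the means were 140 higher and 275 lower shared genes and the maxima 164 and 311. Their noise was drawn from the differences between the induced arrays, which share a slide and scan. Any error particular to the primary array is therefore missing from them, and they may understate the calls shared through it. Part of the overlap may come from the shared primary array, which cannot be split. Among the genes highest in both induced cultures were Clca1 (1080.1-fold), Tff1 (364-fold) and Myh7 (238-fold). Pf4 (7770.2-fold), the cytokine receptor chain Csf2rb (2398-fold) and the macrophage enzyme Acod1 (1789.7-fold) were among the lowest. Without scaling 11715 genes were higher and 978 lower, and with the raised floor 2106 were higher and 2217 lower. Without scaling the thyroid function, epithelial and fibroblast medians were -1.21, -1.73 and 4.60.

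The comparison of the 8-factor with the 7-factor culture asks what adding Hhex changed, on arrays of 1 slide and 1 scan whose spike-in signals differed. Hhex itself was 1.66-fold higher on its brightest probe, a difference of 0.73 under the 2-fold mark, and 30.0-fold higher on its other probe, which lay at -5.67 in the 7-factor and at -0.76 in the 8-factor culture. This second probe was chosen for mention after its value was seen. The other 7 factors differed by less than 2-fold, from -0.36 for Sox2 to 0.63 for Nkx2-1 among those measured on both arrays. The thyroid function list had a negative median with Hhex, but most of its genes differed by less than 2-fold. Of 17 measured genes 4 were lower, 1 higher and 12 under 2-fold. The median of -0.56 lay at percentile 0.09 of matched random lists (central 95% from -0.39 to 0.25). It passed the lower end of that range by less than its bootstrap SD of 0.19, so a shift of the list was left undecided. With normexp background correction the median was -0.34, and without scaling -0.35. Tff3 (4.62-fold), Kcne2 (2.66-fold) and Dio2 (2.01-fold), the genes above primary level, were lower with 8 factors. Dio1 was lower too (2.00-fold), and the sodium-coupled monocarboxylate transporter Slc5a8 was 5.72-fold higher. Tg differed by -0.93 and Duoxa2 by 0.99.

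Interferon-induced genes were higher in the 8-factor culture, with 10 of 19 members higher and 0 lower. The deubiquitinase-like Usp18 was 8.60-fold, the chemokine Cxcl10 8.18-fold, the ubiquitin-like Isg15 4.97-fold and the antiviral protein Rsad2 4.45-fold higher. The list median was 1.14, above all 10000 matched random lists (central 95% from -0.36 to 0.26). Contractile genes were higher in 5 of 12 cases and lower in 0, with calponin Cnn1 at 3.98-fold, leiomodin Lmod1 at 3.93-fold and smooth muscle actin Acta2 at 2.85-fold, and a median of 0.74 above all random lists. The 4 probes of Acta2 were all higher, by 0.49 to 2.15. Stratified epithelium genes had a median of 0.79 (percentile 100; 3 of 14 genes higher and 1 lower), with Krt5 3.69-fold and Krt4 2.32-fold higher and Sprr1a 2.46-fold lower. The inflammation list had a median of 0.43 (percentile 99.97; 2 of 17 genes higher and 1 lower), with Mmp3 3.47-fold and Ccl2 3.13-fold higher and Cxcl2 at least 2.56-fold lower. The inflammation median passed the range of random lists (upper end 0.19) by less than its bootstrap SD of 0.33. A shift of that list was left undecided. The adipocyte list had a median of -0.69 (percentile 0.09). Of its 10 genes 0 were higher, 3 lower and 7 under 2-fold, and the lipid droplet protein Cidec led the lower ones at 3.24-fold. This median passed the range of random lists (lower end -0.47) by less than its bootstrap SD of 0.28, so a shift of the list was left undecided.

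**Figure D4:**
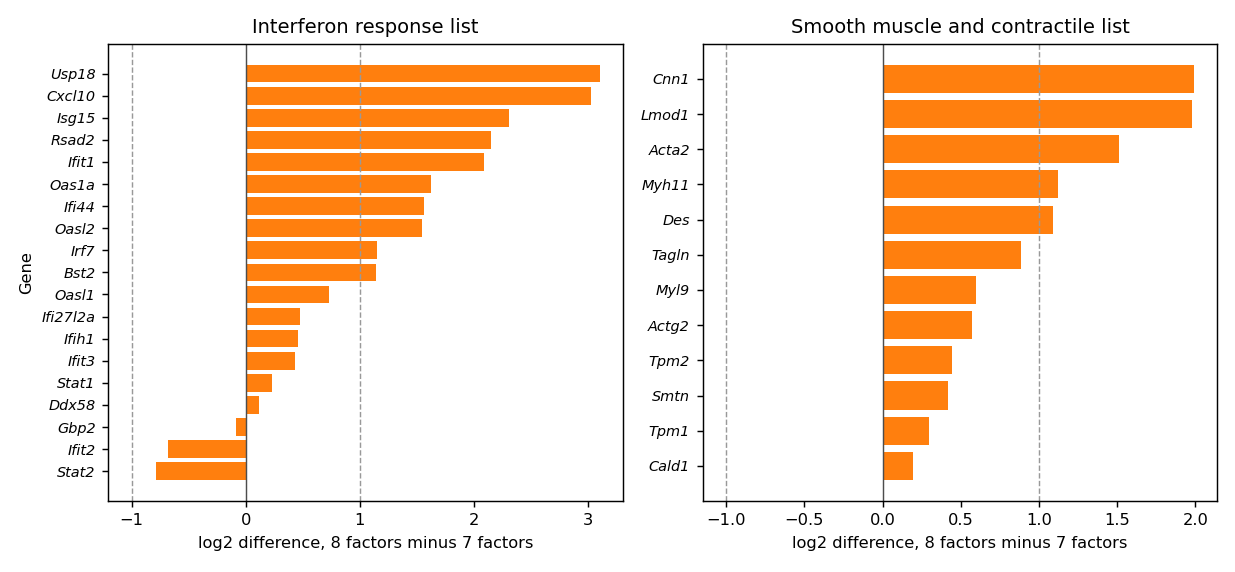
Log2 difference of the 8-factor minus the 7-factor array for each measured member of the interferon response list (left) and of the smooth muscle and contractile list (right), 1 array per culture, with dashed lines at a 2-fold difference. Usp18 reached 3.11 and Cnn1 1.99, and no contractile gene lay below 0.

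The housekeeping list had a median of -0.48 (percentile 1.30), with 3 of 13 genes lower, 0 higher and 10 under 2-fold, Actb being 2.98-fold lower. That median passed the range of random lists (lower end -0.44) by less than its bootstrap SD of 0.15, so a shift of the list was left undecided. Cell cycle genes had a median of 0.09 and ER stress genes one of 0.15, at percentiles 98.5 and 99.1, with 0 members of either at 2-fold. Both passed the range of random lists (upper ends 0.067 and 0.10) by less than their bootstrap SDs of 0.056 and 0.083. Shifts of these lists were left undecided. Fibroblast and matrix genes (-0.20) and epithelial genes (0.11) stayed inside the range of random lists, although fibronectin (Fn1) was 3.24-fold higher and the mesenchymal factor Prrx1 3.14-fold lower. The other probes of Fn1 differed by 1.82 and -0.21, and those of Prrx1 by -1.16, -1.10 and 0.96. Among single genes, the protease inhibitor Tfpi2 was 25.2-fold, the liver transcription factor Creb3l3 20.6-fold and the cardiac stress gene Ankrd1 15.4-fold higher, and the cytochrome Cyp2c23 differed by 4.25. The ferritin-like Fthl17e was 99.9-fold, the monoamine transporter Slc18a2 17.8-fold, Rpgrip1 16.8-fold and Fbxo2 12.9-fold lower. Of the probes of Rpgrip1, another differed by -4.12, whereas the other probes of Fbxo2 differed by -0.39 and -0.18.

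In all, 739 genes were higher and 657 lower in the 8-factor culture, of 16260 compared, and 20 and 8 passed 10-fold. Second probes pointed the same way in 74.3% of 335 genes called on the brightest probe but also passed 2-fold in only 26.9%, so single calls here rest largely on 1 probe. Normexp background correction left 431 higher and 420 lower genes, and without scaling 1200 were higher and 339 lower.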

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

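No test was run for this part. Against primary cells, 17 genes were at least 2-fold higher in one induced culture and at least 2-fold lower in the other, and 4 of them are among the genes chosen for naming. Creb3l3 differed by -2.53 in the 7-factor and 1.83 in the 8-factor culture. The protease gene Mcpt8 differed by -2.35 and 1.66, and Tfpi2 by -3.46 and 1.19, where normexp background correction turned the latter into -0.22. Fthl17e went the other way, with 2.30 and -4.34. These genes stood out because the induced cultures moved in opposite directions. The difference between the cultures was not tested, since each is 1 array.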

How the results depend on the processing

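The alternatives without scaling and with a raised floor were chosen after the results had been seen. Each of the 3 arrays stands alone, so no result could be checked against replicates. No paired analysis was possible because each group has 1 array and the labels give no pairs. A block for slide was not run because the primary array is the only one on its slide. Most results kept their direction under the alternatives run for them, and single genes were not run without scaling or with the raised floor. Of the comparisons with an alternative, 57 counts of genes stayed within 1.5 times the main count and 23 did not, 628 list medians moved by no more than their bootstrap SD, 138 moved further and 16 beyond 2-fold reversed, and all 21 correlations between arrays moved by at most 0.05. For the 175 gene differences of the text, 873 values moved by no more than their scanner error, 315 moved further and 5 reversed. Under normexp background correction alone, 140 moved further, 1 reversed and 33 did not move further, so the size of most folds depends on the background method. The deposited value table and the lack of a filter on dim genes left all 175 as they were, and the filter for both arrays left 144. This was fixed by construction, because the deposited values equal the processed signals and a filter changes no gene's difference. These values are part of the 873 and are no check on the size of a difference. The deposited value table adds to the unmoved counts, list medians and correlations in the same way. The deposited value table gave the same calls as the array files. Without scaling between arrays, genes higher and lower numbered 11208 and 1140 (7 factors against primary), 11715 and 978 (8 factors against primary) and 1200 and 339 (8 against 7 factors), with 10813 and 866 shared by the induced cultures; this alternative adds the same amount to every gene measured on both arrays of a comparison, so such changes follow from its construction. Its medians for the thyroid, fibroblast and epithelial lists were -1.49, 4.48 and -2.24 (7 factors against primary), -1.21, 4.60 and -1.73 (8 factors against primary) and -0.35, 0.013 and 0.32 (8 against 7 factors). Medians below -1 that turned positive without scaling were, for 7 factors against primary, liver 0.18, endothelial 0.70, smooth muscle 1.02, interferon 0.15 and TGF-beta 0.18, and for 8 factors against primary, delivered factors 0.25, endoderm and foregut 0.69, lung 0.058, liver 0.0071, endothelial 0.52, skeletal muscle 0.48, stratified epithelium 0.47, interferon 1.101, inflammation 0.55 and TGF-beta 1.25. Several medians between -1 and 0 turned positive too, among them ER stress (1.23 and 1.40 for 7 and 8 factors against primary). With the floor raised to 25% of the 75th percentile signal, lower genes numbered 2162 and 2217 in the induced cultures against primary cells, with 1854 shared, and 269 higher and 287 lower genes remained between 8 and 7 factors. Medians with the raised floor were -1.96 and 1.82 (thyroid, fibroblast) and -3.47 (epithelial) for 7 factors, -1.54 and 1.84 (thyroid, fibroblast) for 8 factors, and -0.25 for epithelial genes between 8 and 7 factors; the endoderm and foregut median for 8 factors against primary reversed to 2.14. Raising the floor takes out dim genes by construction. With no filter on dim genes, lower genes numbered 7133 and 7198, with 6324 shared, because the floor of the primary array lies higher than that of the others after scaling. A 3-fold threshold gave 1591 and 1486 higher genes against primary cells (1176 shared) and 238 higher and 109 lower between 8 and 7 factors, fewer by construction. Normexp background correction gave 431 higher and 420 lower genes between 8 and 7 factors, fibroblast medians of 1.71 and 1.56 and epithelial medians of -3.18 and -3.31 for 7 and 8 factors against primary, and a thyroid median of -0.34 between 8 and 7 factors; quantile normalization gave a fibroblast median of -0.064 there. Normexp also took Tfpi2 to -0.22 in the 8-factor culture against primary cells. With the median over probes, Col6a3 and Ncam1 became -0.73 and -0.29 (7 factors against primary) and Myc became -0.38 and -0.18 (7 and 8 factors against primary), because this alternative takes the median level on each array, which can fall on different probes or on a floored value, and not the median of the probes' differences. Apart from the causes named, the cause was not tested. Signal over background limits the primary array most, with 64.2% of spots well above it against 78.2% on each induced array, so differences of genes dim there are bounds.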

Other observations

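Xist, the RNA that coats the silent X chromosome of female cells, lay at 4.01 in the 7-factor and 3.30 in the 8-factor culture. In primary cells it was not well above background (-7.22), so it was at least 574-fold and at least 349-fold higher in the induced cultures. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were above background on every array. Ddx3y lay at 0.61, 0.52 and 0.94 in the 7-factor, 8-factor and primary cultures, and Eif2s3y at 0.67, 1.36 and 1.97. These levels leave open that the cultures differed in the sex of their cells. Such a difference could not be told apart from group in any comparison with primary cells. Tsix, the antisense partner of Xist, lay at -0.23 in the 7-factor and -3.20 in the 8-factor culture.

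Single genes of other lineages differed between the cultures. The 7-factor culture had more of the endoderm factor Gata6 than primary cells (log2 difference 3.52, other probes 1.46 and 0.21). It also had more of the neural genes Fabp7 (11.7-fold) and Ncam1 (7.08-fold, with other probes from -1.65 to 4.10). The lipase Lpl (8.72-fold), the fibrillar collagen Col11a1 (26.8-fold) and the secreted Wnt inhibitor Sfrp4 (at least 270.4-fold) were higher too. Other members of the same lists were lower in this comparison. They numbered 6 of 14 for endoderm and foregut, 5 of 15 for neural and glial, 2 of 10 for adipocyte and 3 of 12 for cartilage and bone genes. Primary cells had more of the protease Napsa (805-fold), osteopontin Spp1 (21.4-fold), Plekhd1 (1162-fold) and the vessel marker Emcn (15.3-fold). Between the induced cultures, the 8-factor culture had more of the neuroendocrine chaperone Scg5 (5.29-fold), the kidney androgen-regulated gene Kap (8.05-fold) and the antigen presentation gene Cd74 (6.81-fold). Foxa1, an endoderm factor, was 3.21-fold lower there, and the probes of the ubiquitous gene Ywhaz differed by -1.70 and 1.42.

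The tests in the rest of this part were all chosen after the results had been seen. After scaling, dim genes were lower in the induced cultures, with a median difference of -1.93 in the dimmest of 10 groups for 7 factors against primary cells. Close to background a signal reflects the amount of labelled RNA only in part, so a dimmer primary array may raise its dim genes once arrays are scaled. Without scaling the dimmest group had a median difference of 0.19 and the middle groups 2.28 and 2.32, but this decides nothing, because leaving out scaling moves every group by the same amount. The genes of the dimmest group also had to exceed the floor of each array, which lies higher on the primary array after scaling and by itself favours lower values. The explanation stays open, and a real loss of rare transcripts in the induced cultures was not tested.

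Leukocyte genes formed the largest shift of any list. Scaling of the dimmer primary array is excluded as its whole cause, because the median of 7 factors against primary cells was still -4.47 without scaling. The other explanation is that the primary culture held leukocytes, such as macrophages, and this may account for the pattern: 14 of 19 list genes with a probe lay above the 75th percentile signal of the primary array, 18 lay above background there, and 0 lay above the 75th percentile on either induced array. These levels follow in part from the difference itself, so they leave that explanation open, and the presence of parathyroid and C cells was not tested.

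Interferon genes were the list most raised by 8 over 7 factors. Errors that differ from probe to probe are excluded as the whole cause, because the list median of 1.14 lay far above the range of matched random lists (-0.36 to 0.26). A shift between the arrays that depends on signal is excluded too, because random lists matched on signal had a median of -0.058. Hhex itself, the further virus given with it or a chance difference between 2 cultures could each have raised these genes, and with 1 culture of each kind these were not tested.

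Several of the genes highest in the induced cultures (Tff1, Tff3, Gkn2, Clca1) are made by mucous cells of stomach and gut, which led to the hypothesis that such genes are higher as a group. A list of other gastric and intestinal mucous genes, written after those genes had been seen and without them, was compared with matched random lists. Its median for 7 factors against primary cells was 0.70, at percentile 99.5, with 8 of 18 measured genes higher and 5 lower; for 8 factors against primary cells it was 0.70, at percentile 98.8. The bootstrap SD of these medians was 0.59 and 0.69, so each reached above the range of random lists (upper ends 0.38 and 0.54) by less than its own spread, and the hypothesis was left undecided.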
